A study of Mus musculus with 103 samples.

How the data were processed

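PolyA-selected RNA was sequenced from mouse pancreatic carcinoma (KPC) cells that carry a doxycycline-inducible shRNA against Myc, and from tumors grown from such cells after transplantation into the pancreas. Per the labels' protocols, cultured cells received 1 µg/ml doxycycline or ethanol for 48 h, tumors grew for 7 or 14 days before the drug was given in food (for 48 h in tumors A, and for 48 h or in some experiments until the end for tumors B), and libraries were made with NEBNext Ultra kits and run on a NextSeq500. Libraries in 6 tables were used: KPC cells (6 libraries), a first set of tumors (tumors A, 10 libraries), a second set of tumors (tumors B, 12 libraries), cells that also express inducible Myc-WT or Myc-VD (MycVD table, 12 libraries), EV and TBK1ko cells (TBK1 table, 12 libraries), and cells with wild-type or knocked-out TBK1 that express IKBa or IKBaM (IKBa table, 24 libraries). The names tumors A and tumors B are shorthand used here. The 4SU pulse and chase groups and the double-stranded RNA pull-down groups were not analysed here.

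The values deposited by the authors for each library are read counts per gene with no normalization. Per the submitters' processing notes, bcl2fastq, FastQC, Bowtie2 and edgeR were used with the builds mm9 and mm10 (mm10 and hg19 for tumors B), without versions. The counting program, the annotation release and the strand of counting are not given in the sources used here. Because the strand was not stated, reads from overlapping or antisense genes could not be told apart. Library totals within the KPC, tumors A and IKBa tables were nearly equal, so reads may have been drawn to a common depth before counting, which no source states. The authors also deposited tables with a log2 fold change, a mean log2 CPM, a p-value and an adjusted p-value per gene for 4 comparisons; the method of adjustment is not given in the sources used here. A further deposited table holds 18917 genes of both tumor sets as a normalized count signal, scaled by the authors to a total of 6 M (mega-counts) per library with a largest relative deviation of 1.81e-05. These tables served only for comparison, and all statistics below were computed from the deposited counts unless a sentence names the authors' deposited table.

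Depth ranged from 5.65 to 5.81 M counts per library in the KPC table, 9.18 to 9.54 in tumors A, 10.1 to 23.2 in tumors B, 9.68 to 13.6 in the MycVD table, 7.87 to 10.3 in the TBK1 table and 9.08 to 9.20 in the IKBa table. No pair of libraries held identical values. Scatter between replicates reached at least that of counting noise in every group (lowest chi-square per gene and degree of freedom 1.14). The first principal component took 85.7% of the variance in the KPC table, 37.2% in tumors A, 38.5% in tumors B, 39.1% in the MycVD table, 45.5% in the TBK1 table and 38.4% in the IKBa table.

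Before the data were examined, the groups, the 20 comparisons, the tests, the 23 gene lists, the rule for naming genes and most alternatives were fixed. Differential expression was tested per table with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by group, robust quasi-likelihood fit, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05). Genes tested were 14313 of 15214 in the KPC table, 19601 of 19729 in tumors A, 19570 of 19783 in tumors B, 18917 for both tumor sets together, 17852 of 17852 in the MycVD table, 17975 of 18241 in the TBK1 table and 18375 of 18550 in the IKBa table. All groups of a table shared 1 fit. The tumor sets were analysed together with the experiment as a block. Differences of the doxycycline response between lines or tumor sets were tested as interactions, and a response is called higher or lower by its signed log2 fold change. All values after ± are standard errors for log2 fold changes and standard deviations for levels, and CPM values are means over a group. The p-values measure only the spread between these libraries, which may be technical, since replicates of a line are cultures of 1 line.

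Gene lists were tested with camera from limma 3.58.1 on voom log2-CPM with a preset correlation of 0.01, adjusted over the lists of a comparison; at least 5 tested members were needed. The lists were ribosome biogenesis, nucleotide, polyamine and one-carbon metabolism, spliceosome and snRNP assembly, interferon-stimulated genes, double-stranded RNA sensing, NF-kB targets, MHC class I antigen presentation, vesicle transport, lysosome, cell cycle, ATF4 stress response, mitochondrial translation, and markers of epithelial and ductal, mesenchymal, T and NK, B and plasma, macrophage and monocyte, neutrophil, dendritic, fibroblast, endothelial, acinar and islet, and adipocyte and muscle cells. For each list the number of members past the gene test is given over all genes and, where it differed, after adjustment over the list alone. A response set was taken from KPC cells (adjusted p under 0.05 and an absolute log2 fold change of at least 1, alternative 0.5) and tested by camera in the other 5 tables only. A TBK1-dependent set, the members of the KPC up set with a negative interaction of TBK1ko and EV cells, was tested only in the IKBa table. Named genes are the manipulated genes Myc, Tbk1, Ikbke and Nfkbia, a fixed panel of genes (among them Ifit1, Isg15, Oasl1, Irf7, Cxcl10, Ccl5, Ccl2, Nfkb1, Tnfaip3, H2-K1, B2m, Tap1, Odc1, Ncl, Nop56, Cad, Cdk4, Srsf1, Vamp4 and Cdkn1a), up to 6 largest rises and 6 largest falls per comparison (adjusted p under 0.05, mean log2-CPM of at least 2, no overlap between groups), and up to 2 members per list with the lowest p. A few genes that this rule names are not reported here. Correlations between experiments were computed across genes, which are not independent replicates, and carry no p-value.

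Alternatives were DESeq2 1.42.0, RLE factors, no filter, each library left out, only the groups of a comparison in the fit, a replicate block, marker scores as covariates in tumors B, the experiment left out of the design, limma on the authors' combined table, camera with an estimated correlation, and fry. Leaving out both doxycycline tumors that lay apart on the first principal component, and a replicate block for the response sets, were chosen after seeing the data. Replicate numbers were checked by correlating deviations from group means. In the MycVD table, same-numbered libraries deviated together (0.257 to 0.35 for replicate 1, 0.434 to 0.522 for replicate 2, 0.6 to 0.701 for replicate 3), so they were treated as pairs in a blocked fit. Camera with an estimated correlation and fry were run only without the block, so for the MycVD table they ignore this pairing. The blocked value is printed beside a result of the report where it changed the call or the count, and other changed calls are gathered in the closing section.

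The test was tried on simulated counts with 200 genes changed. At 1.5-, 2- and 4-fold changes, 64.2, 92.4 and 100% of them were recovered for KPC cells (14150 genes), 67.2, 89.6 and 97% for EV cells (17700 genes), 61.2, 85.1 and 98.5% for TBK1wt IKBa cells (17922 genes), 40.3, 68.7 and 98.5% for MycVD against MycWT (17826 genes), 29.9, 68.7 and 93.9% for the TBK1 interaction (17664 genes), 3, 54.5 and 81% for tumors A (19311 genes) and 25.4, 52.2 and 93.7% for tumors B (19506 genes). Between 0.8 and 6.6% of the calls were false. Group labels were also exchanged between libraries to see how many genes such a split would call.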

Results

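MYC is a transcription factor that drives growth in pancreatic carcinoma. The data ask which transcripts change when MYC is depleted in cultured tumor cells and in tumors, whether the kinase TBK1 or signaling held back by IKBa is needed for the changes, and whether re-expressed Myc-WT or Myc-VD returns them. Each cell group held 3 libraries, each group of tumors A 5 and each group of tumors B 6.

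The Myc transcript fell under doxycycline in all 7 cell lines that carry only the shRNA as a source of change in Myc. In KPC cells it went from 193 ± 9.83 to 116 ± 16.7 CPM (log2 fold change -0.73 ± 0.07, adjusted p = 3.3e-11). In EV cells it went from 124 ± 2.01 to 52.9 ± 5.56 CPM (-1.24 ± 0.07, adjusted p = 9.8e-11) and in TBK1ko cells from 165 ± 5.67 to 80.6 ± 3.85 CPM (-1.03 ± 0.07, adjusted p = 1.5e-09). In the IKBa table it went from 129.5 ± 10.7 to 66.6 ± 0.985 CPM in TBK1wt IKBa cells and from 129 ± 4.47 to 67.0 ± 5.96 in TBK1ko IKBa cells (log2 fold changes -0.96 and -0.94). With IKBaM it went from 132.5 ± 3.81 to 59.8 ± 3.06 in TBK1wt IKBaM cells and from 130.1 ± 6.25 to 60.3 ± 5.81 in TBK1ko IKBaM cells (-1.15 and -1.11). In cells with inducible Myc-WT or Myc-VD the summed Myc counts rose from 119 ± 20.7 to 325 ± 88.9 CPM and from 131 ± 17.7 to 378 ± 93.7 CPM. Tumors were less certain, with 101 ± 16.1 against 48.5 ± 18.7 CPM in tumors A (adjusted p = 0.133) and 100.4 ± 13.4 against 78.2 ± 17.4 CPM in tumors B (adjusted p = 0.264).

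The other manipulated genes matched their labels in part. Tbk1, the kinase that activates IRF3 downstream of nucleic acid sensors, was read at 33.9 ± 1.18 CPM in EV and 24.2 ± 1.60 CPM in TBK1ko controls, and at 42.5 ± 1.15 CPM in TBK1wt IKBa against 24.6 ± 2.17 CPM in TBK1ko IKBa controls. The knockout lines thus kept Tbk1 reads, and counts per gene cannot show whether these come from an intact transcript. Nfkbia, which codes for IKBa, stood at 675 ± 36.8 CPM in TBK1wt IKBaM and 461 ± 28.2 CPM in TBK1ko IKBaM controls. In TBK1wt IKBa and TBK1ko IKBa controls it stood at 48.0 ± 2.22 and 30.4 ± 1.75 CPM, so a raised Nfkbia level was seen only in the lines with the mutant. Per the labels' protocols doxycycline induces IKBaM, yet Nfkbia was high without it and fell under it, to 448.5 ± 41.7 and 232 ± 4.80 CPM. The control and doxycycline groups of these lines thus differ in MYC and also in the Nfkbia level, which was raised in both.

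**Figure D1:**
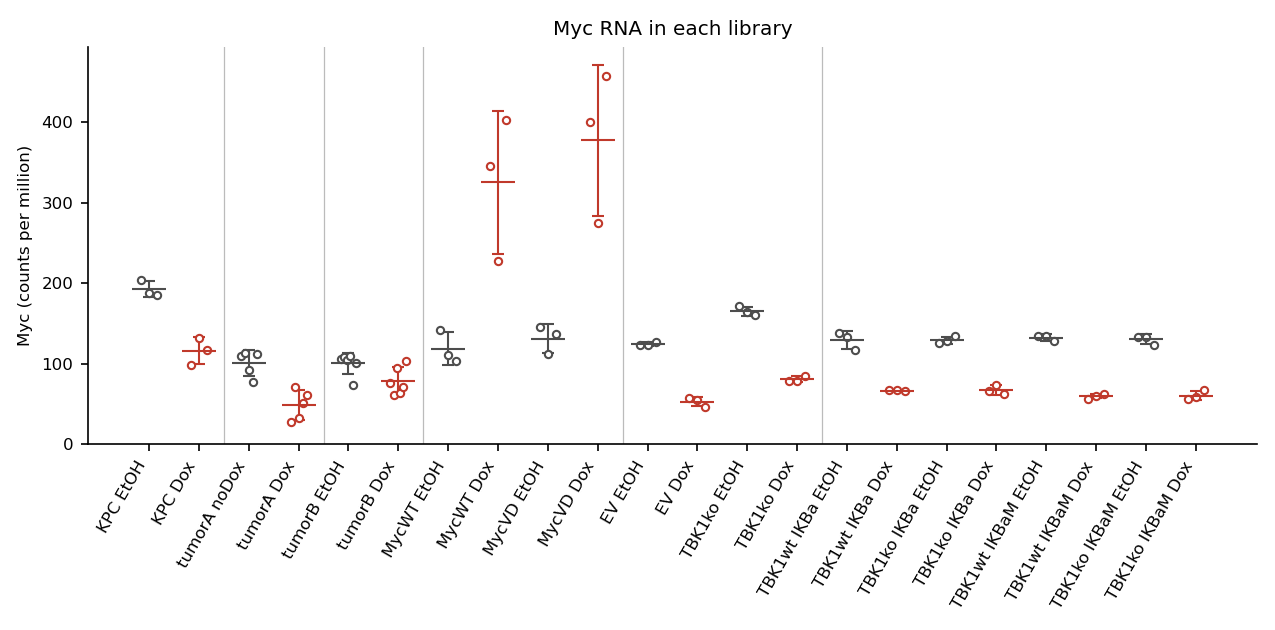
Myc level (CPM) per library in every group, with mean and standard deviation; grey marks control and red marks doxycycline.

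The first comparison asks what MYC depletion does in KPC cells. Transcripts for ribosome production fell most evenly. Ncl, which codes for the nucleolar protein nucleolin, went from 2290 ± 78.6 to 412 ± 23.2 CPM (5.56-fold lower, adjusted p = 1.6e-31), and Npm1, its partner in the nucleolus, fell by 1.96 ± 0.05 in log2 units. Nop56, a core protein of box C/D particles, fell from 328 ± 4.19 to 97.9 ± 2.68 CPM, and all 36 tested members of the ribosome biogenesis list fell (median -1.35, adjusted p = 9.7e-20). In the nucleotide, polyamine and one-carbon list 22 of 27 members fell and 2 rose (median -1.02, adjusted p = 1.1e-08). Cad, the first enzyme of pyrimidine synthesis, fell from 204 ± 14.5 to 52.0 ± 6.52 CPM, and the spermidine synthase Srm from 148 ± 13.3 to 31.6 ± 4.49 CPM. Odc1, a textbook MYC target of the same list, rose instead (0.48 ± 0.05, adjusted p = 1.7e-10).

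Splicing, division and mitochondrial ribosomes followed. Of 38 spliceosome and snRNP assembly genes 36 fell (median -0.67, adjusted p = 5.0e-12). Among them were Gemin5, which reads snRNA for the SMN complex (-1.74 ± 0.08), Wdr77, a subunit of the PRMT5 methylosome (-1.29 ± 0.06), and the splicing factor Srsf1 (581 ± 33.6 to 283 ± 13.9 CPM). Of 39 cell cycle genes 37 fell (median -0.66, adjusted p = 3.4e-11). They had the mitotic kinase Aurkb at -2.06 ± 0.09, Ccna2 at -1.03 ± 0.06 and Cdk4 at -0.39 ± 0.06. The cell cycle inhibitor Cdkn1a rose from 5.30 ± 1.25 to 27.0 ± 2.37 CPM. Of 28 mitochondrial translation genes 25 fell (median -0.54, adjusted p = 9.2e-06), for example Mrps30 (-0.97 ± 0.10) and Mrpl12 (-0.82 ± 0.07). The ATF4 stress response split, with 7 members up and 12 down (median -0.20, adjusted p = 0.0866). The amino acid transporter Slc7a5 (-1.34 ± 0.07) and the serine synthesis enzyme Psat1 (-1.13 ± 0.06) were on the falling side.

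Immune and secretory transcripts rose in the same cells. H2-K1, a classical MHC class I heavy chain, rose from 29.8 ± 3.9 to 205 ± 13.0 CPM (6.86-fold, adjusted p = 1.0e-26), with H2-D1 at 1.15 ± 0.07 and its light chain B2m at 0.95 ± 0.10. Of 16 MHC class I genes 10 rose and 2 fell (median 0.81, adjusted p = 0.0165, adjusted p = 0.196 with an estimated correlation). Among 27 NF-kB targets 18 rose and 2 fell (median 0.48, adjusted p = 0.000363). The list was led by Tnfaip3, a feedback inhibitor of the pathway (80.7 ± 3.15 to 262 ± 2.40 CPM), and Ptgs2, the inducible cyclooxygenase (228 ± 19.2 to 716 ± 65.5 CPM). Of 16 interferon-stimulated genes 11 rose (median 0.51, adjusted p = 0.0075, adjusted p = 0.0929 with an estimated correlation). They included Stat2 (1.61 ± 0.14) and Irgm1 (0.77 ± 0.08). Of 18 genes of double-stranded RNA sensing 10 rose and 4 fell (median 0.37, adjusted p = 0.0453, adjusted p = 0.118 with an estimated correlation). The TLR3 adaptor Ticam1 rose by 1.67 ± 0.12, the TBK1-related kinase Ikbke by 0.73 ± 0.10 and Tbk1 itself by 0.29 ± 0.09.

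Membrane traffic and lysosomes also rose. Of 49 vesicle transport genes 38 rose and 3 fell (39 and 3 adjusted over the list alone, median 0.39, adjusted p = 1.7e-06, adjusted p = 0.0634 with an estimated correlation). The tetraspanin Cd63 stood at 1.47 ± 0.07, Vamp8 at 1.29 ± 0.08 and Vamp4 at 0.62 ± 0.12. Of 33 lysosome genes 26 rose and 3 fell (median 0.87, adjusted p = 1.3e-08, adjusted p = 0.0811 with an estimated correlation). The protease Ctsl rose 4.23-fold and progranulin, Grn, 4.01-fold. Of 8 mesenchymal markers 6 rose (7 adjusted over the list alone, median 1.04, adjusted p = 0.00258, adjusted p = 0.0625 with an estimated correlation). The matrix protein Sparc rose by 1.23 ± 0.06. Of 12 epithelial markers 9 rose and 2 fell (median 0.53, adjusted p = 0.0164, adjusted p = 0.29 with an estimated correlation). The largest rises were Synpo2l (5.44 ± 0.32), Nppb (31.9-fold) and Podnl1 (4.44 ± 0.29), and the largest fall Lhfp (56.5 ± 2.49 to 3.07 ± 0.546 CPM). In total 10017 of 14313 genes passed, 4966 up and 5051 down, of which 1398 rose and 1086 fell at least 2-fold. Counts were scaled per library, so rises and falls throughout are relative and RNA per cell was not measured. The authors' deposited table calls 10283, and 9896 genes are called in both in the same direction. With 3 cultures of 1 line per group, such a count mirrors small spread between cultures. Doxycycline itself was not separated from loss of MYC.

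**Figure D2:**
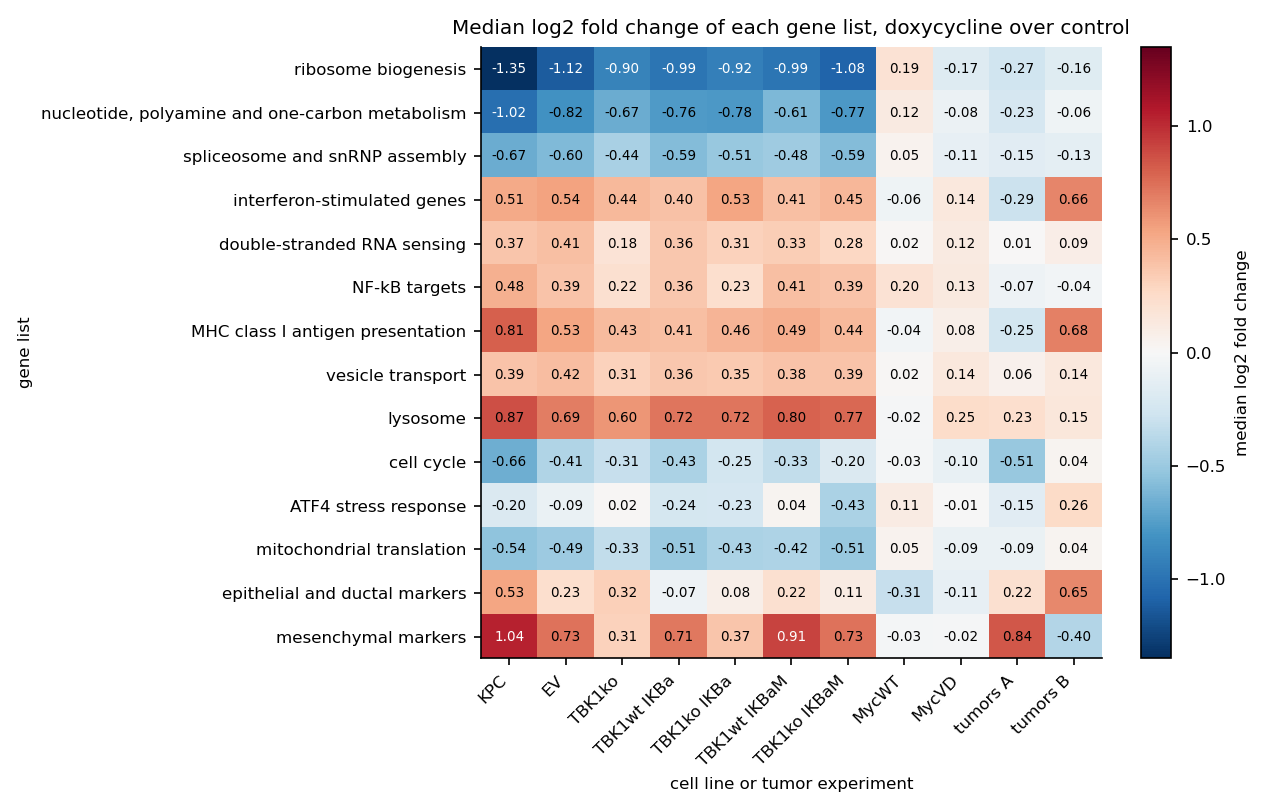
Heat map of the median log2 fold change of 14 gene lists in 11 comparisons, from blue (lower under doxycycline or in the first group named) to red (higher).

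Knockdown in EV cells and in TBK1wt IKBa cells asks whether the response recurs in libraries made separately. In EV cells 10376 of 17975 genes passed (5557 up, 4819 down), and in TBK1wt IKBa cells 10334 of 18375 (5418 up, 4916 down). Ncl fell from 2085 ± 209 to 584 ± 13.6 CPM in EV cells and by 1.73 ± 0.06 in TBK1wt IKBa cells, and all 37 ribosome biogenesis genes fell in both (medians -1.12 and -0.99, adjusted p = 1.3e-24 and 2.1e-28). The RNA helicase Ddx21 (-1.33 ± 0.06), the purine enzyme Atic (-1.32 ± 0.06) and Hnrnpa1 (-1.20 ± 0.08) fell in EV cells, and the pseudouridine synthase Dkc1 (-1.67 ± 0.06) in TBK1wt IKBa cells. The nucleotide list had 1 member up and 23 down in EV cells and 3 up and 23 down in TBK1wt IKBa cells (medians -0.82 and -0.76). Spliceosome genes fell in 36 and in 38 of 38 cases (medians -0.60 and -0.59), and cell cycle genes in 28 and in 38 of 39 (medians -0.41 and -0.43).

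The inflammatory side recurred as well. Tnfaip3 rose from 39.4 ± 5.36 to 122 ± 2.94 CPM in EV cells and from 41.4 ± 2.98 to 127 ± 4.06 CPM in TBK1wt IKBa cells, and Ptgs2 from 324 ± 32.2 to 1077 ± 38.8 CPM in EV cells. NF-kB targets rose in 19 of 29 cases in EV cells, with 2 falling, and in 17 of 30 in TBK1wt IKBa cells, with 2 falling (3 adjusted over the list alone, medians 0.39 and 0.36, adjusted p = 0.00204 and 0.00102). H2-K1 rose from 31.7 ± 1.88 to 65.9 ± 1.94 CPM and by 1.15 ± 0.08. The MHC class I list (median 0.53, adjusted p = 0.00559 in EV, and 0.41, adjusted p = 0.0307 in TBK1wt IKBa) gave adjusted p = 0.142 and adjusted p = 0.201 with an estimated correlation. Interferon-stimulated genes rose in 12 of 19 cases in EV cells (13 adjusted over the list alone) and 14 of 23 in TBK1wt IKBa cells, with 1 falling in each (medians 0.54 and 0.40, adjusted p = 0.00972 and 0.019). Stat2 rose by 1.22 ± 0.15 and 1.11 ± 0.15. The double-stranded RNA list held 14 rises and 2 falls in EV cells (15 and 2 adjusted over the list alone, median 0.41, adjusted p = 0.0222, adjusted p = 0.229 with an estimated correlation). In TBK1wt IKBa cells it held 17 rises and 3 falls (median 0.36, adjusted p = 0.0118, adjusted p = 0.0725 with an estimated correlation). Ticam1 rose by 1.12 ± 0.13 and 1.24 ± 0.12, and Ikbke by 0.70 ± 0.14 and 0.78 ± 0.10. The feedback inhibitor Nfkbia rose by 0.39 ± 0.10 and 0.41 ± 0.07.

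Lysosome genes rose in 26 of 33 cases in EV and 27 in TBK1wt IKBa cells, with 2 falling in each (medians 0.69 and 0.72), for example the ceramidase Asah1 by 0.89 ± 0.05 in EV cells and the proton pump subunit Atp6v0d1 by 1.28 ± 0.06 in TBK1wt IKBa cells. Vesicle transport genes rose in 40 of 49 cases (41 up and 1 down adjusted over the list alone) and in 38, with 1 falling (39 and 1 adjusted over the list alone, medians 0.42 and 0.36), such as the SNARE protein Snap29 in EV cells (1.12 ± 0.10). Mesenchymal markers rose in 7 of 9 and 7 of 10 cases, with 2 falling in TBK1wt IKBa cells (medians 0.73 and 0.71, adjusted p = 0.0014 and 0.0118). Mitochondrial translation genes fell in 22 of 28 cases in EV cells (23 adjusted over the list alone, median -0.49, adjusted p = 6.6e-07, adjusted p = 0.0736 with an estimated correlation) and in 25 in TBK1wt IKBa cells (median -0.51). The KPC up set rose in 1180 of 1289 cases in EV cells and 1167 of 1284 in TBK1wt IKBa cells (medians 0.97 and 0.95, adjusted p = 2.9e-51 and 1.0e-58). The down set fell in 894 of 986 and 790 of 881 (medians -0.92 and -0.86). Across genes, which are not independent replicates, log2 fold changes correlated at 0.86 between KPC and EV, 0.85 between KPC and TBK1wt IKBa, and 0.86 between EV and TBK1wt IKBa cells. In all, 3294 genes rose and 2743 fell in all 3 of 12610 tested. Supt3, a SAGA complex subunit, was the largest rise in EV cells (14.3 ± 1.51 to 253 ± 4.72 CPM), followed by Frmpd1 (3.94 ± 0.17) and the small heat shock protein Cryab (3.48 ± 0.20).

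**Figure D3:**
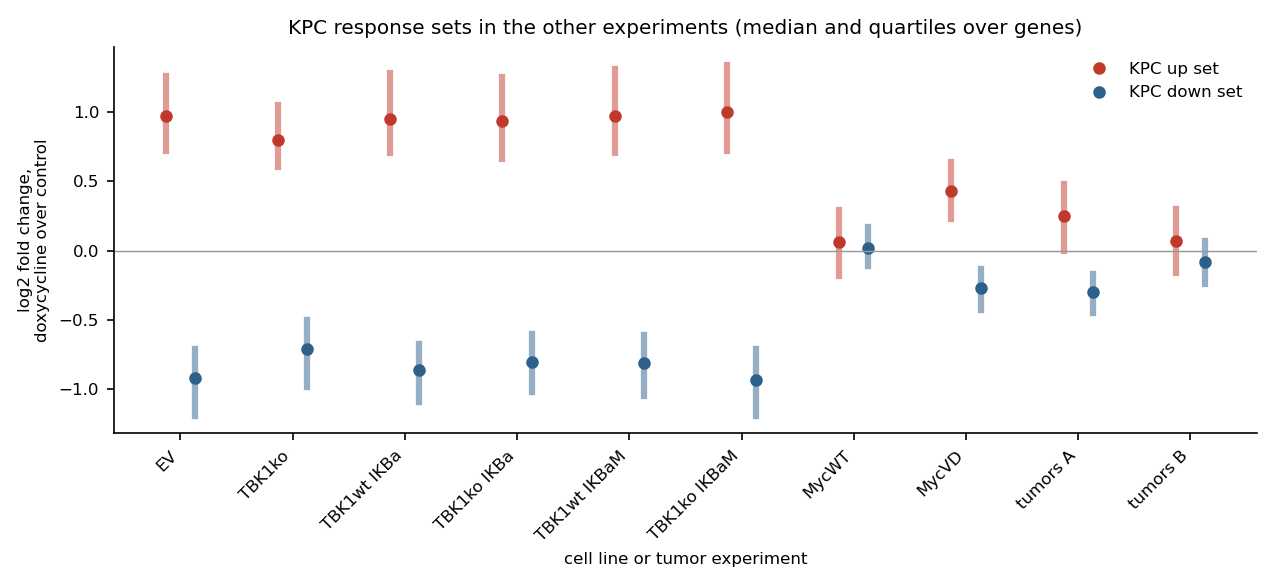
Median and quartiles of the log2 fold changes of the KPC up set and down set in 10 comparisons of the other tables.

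Knockdown in TBK1ko cells, and its difference from EV cells, asks what of the response needs TBK1. In TBK1ko cells 8114 genes passed (4088 up, 4026 down). Ncl fell from 2134 ± 56.3 to 804 ± 12.5 CPM and all 37 ribosome biogenesis genes fell (median -0.90, adjusted p = 3.2e-26). Tnfaip3 rose from 61.4 ± 6.25 to 119 ± 3.96 CPM, H2-K1 from 5.36 ± 0.264 to 11.6 ± 1.27 CPM and Ptgs2 from 944 ± 56.6 to 1655 ± 103 CPM. NF-kB targets rose in 13 cases and fell in 2 (14 and 2 adjusted over the list alone, median 0.22, adjusted p = 0.0102). The MHC class I list (10 up, 2 down, and 11 and 2 adjusted over the list alone) had a median of 0.43 (adjusted p = 0.000967, adjusted p = 0.0921 with an estimated correlation). The interferon list (8 up, 1 down) had 0.44 (adjusted p = 0.0398, adjusted p = 0.0818 with an estimated correlation). Lysosome genes rose in 27 cases (28 up and 1 down adjusted over the list alone, median 0.60), such as the protease Ctsd (1.05 ± 0.07), and vesicle genes in 30 (32 adjusted over the list alone, median 0.31). The KPC up set rose in 1085 and the down set fell in 830 cases (medians 0.80 and -0.71).

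The interaction named 649 genes, 268 with a higher and 381 with a lower response in TBK1ko cells. RLE factors gave 508 higher and 289 lower. Among NF-kB targets the response of Tnfaip3 was lower by 0.68 ± 0.12 (adjusted p = 0.00773), that of Ptgs2 by 0.92 ± 0.10 (adjusted p = 3.2e-05). That of Csf1 was lower by 1.39 ± 0.16 (32.0 to 51.0 CPM in EV, 25.8 to 15.7 CPM in TBK1ko). Ptgs2 and Tnfaip3 still rose in TBK1ko cells, from higher control levels than in EV cells (944 against 324 and 61.4 against 39.4 CPM). The NF-kB list held 1 higher and 3 lower members (1 and 5 adjusted over the list alone, median -0.13, adjusted p = 0.0151, adjusted p = 0.0666 with an estimated correlation). Fibronectin, Fn1 (-1.25 ± 0.32), was lower, as was Ifit2 (-0.71 ± 0.17), while Isg20, also interferon-stimulated, was higher (0.53 ± 0.14, adjusted p = 0.04). H2-K1 (0.04 ± 0.16, adjusted p = 0.929) and B2m (-0.23 ± 0.14, adjusted p = 0.364) had no difference that passed. The fall of ribosome biogenesis genes was smaller in TBK1ko cells. In this list 8 members were higher (19 adjusted over the list alone, median 0.24, adjusted p = 2.2e-10). The KPC up set responded less (2 higher, 89 lower, median -0.17, adjusted p = 1.7e-06) and the down set too (69 higher, 3 lower, median 0.22, adjusted p = 1.9e-12). Part of the difference thus ran through the whole response. Myc fell less too, short of the threshold (0.20 ± 0.10, adjusted p = 0.259), so weaker knockdown may take part.

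Other lists shifted less. Spliceosome genes (median 0.19, 2 higher, adjusted p = 0.00392, adjusted p = 0.0626 with an estimated correlation), cell cycle genes (0.07, 2 higher, 3 adjusted over the list alone, adjusted p = 0.0151, adjusted p = 0.0626 with an estimated correlation) and mitochondrial translation (0.12, 1 higher, adjusted p = 0.0127, adjusted p = 0.308 with an estimated correlation) were higher. Vesicle transport (-0.13, 4 lower, 1 higher and 7 lower adjusted over the list alone, adjusted p = 0.0127, adjusted p = 0.103 with an estimated correlation) and double-stranded RNA sensing (-0.22, 1 lower, Tbk1 itself, adjusted p = 0.04, adjusted p = 0.308 with an estimated correlation) were lower. The largest differences were those of Supt3 (-4.38 ± 0.16, adjusted p = 1.1e-12) and the bone transcription factor Runx2 (-2.89 ± 0.12), which rose only in EV cells, and of the tRNA methyltransferase Alkbh8 (2.20 ± 0.15), which rose only in TBK1ko cells. Supt3 and Runx2 lie in 1 region, and the strand of counting was not stated. The count of 649 moved to 256 without EV control replicate 2, 2722 without control replicate 3, and 323, 99 and 113 without EV doxycycline replicates 1, 2 and 3. It moved to 178 and 106 without TBK1ko control replicates 1 and 2, and to 129, 158 and 1031 without TBK1ko doxycycline replicates 1, 2 and 3. With 1 line per genotype, TBK1 and other differences between lines cannot be separated, and the labels' characteristics list TBK1 knockout and siRNA against IKBKE for all 12 libraries of this table.

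The level of TBK1ko against EV cells under doxycycline differed at 7117 genes (3433 higher, 3684 lower). The authors' deposited table calls 8248, with 7050 in both in the same direction. Tbk1 itself was lower by 1.32 ± 0.11 and Ikbke by 1.12 ± 0.15. H2-K1 was 5.73-fold lower (65.9 against 11.6 CPM, adjusted p = 1.3e-13), B2m lower by 0.62 ± 0.10, Krt7 lower by 4.32 ± 0.10, Sparc lower by 2.64 ± 0.07 and Csf1 lower by 1.70 ± 0.11. Such gaps were also present without doxycycline, with Sparc at 388 against 62.9 CPM and H2-K1 at 31.7 against 5.36 CPM in EV and TBK1ko controls, so they do not measure the response to MYC depletion. Tnfaip3 stood level (-0.04 ± 0.08, adjusted p = 0.752), Ifit3 was higher by 1.63 ± 0.21 and Oasl1 lower by 0.96 ± 0.10. Ribosome biogenesis genes were higher (27 up, 1 down, and 30 and 1 adjusted over the list alone, median 0.40, adjusted p = 4.7e-10), with Dkc1 at 0.99 ± 0.09, and Myc was higher by 0.61 ± 0.08. Of the response sets, the KPC up set was lower (160 up, 540 down, median -0.23) and the down set higher (412 up, 81 down, median 0.28).

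**Figure D4:**
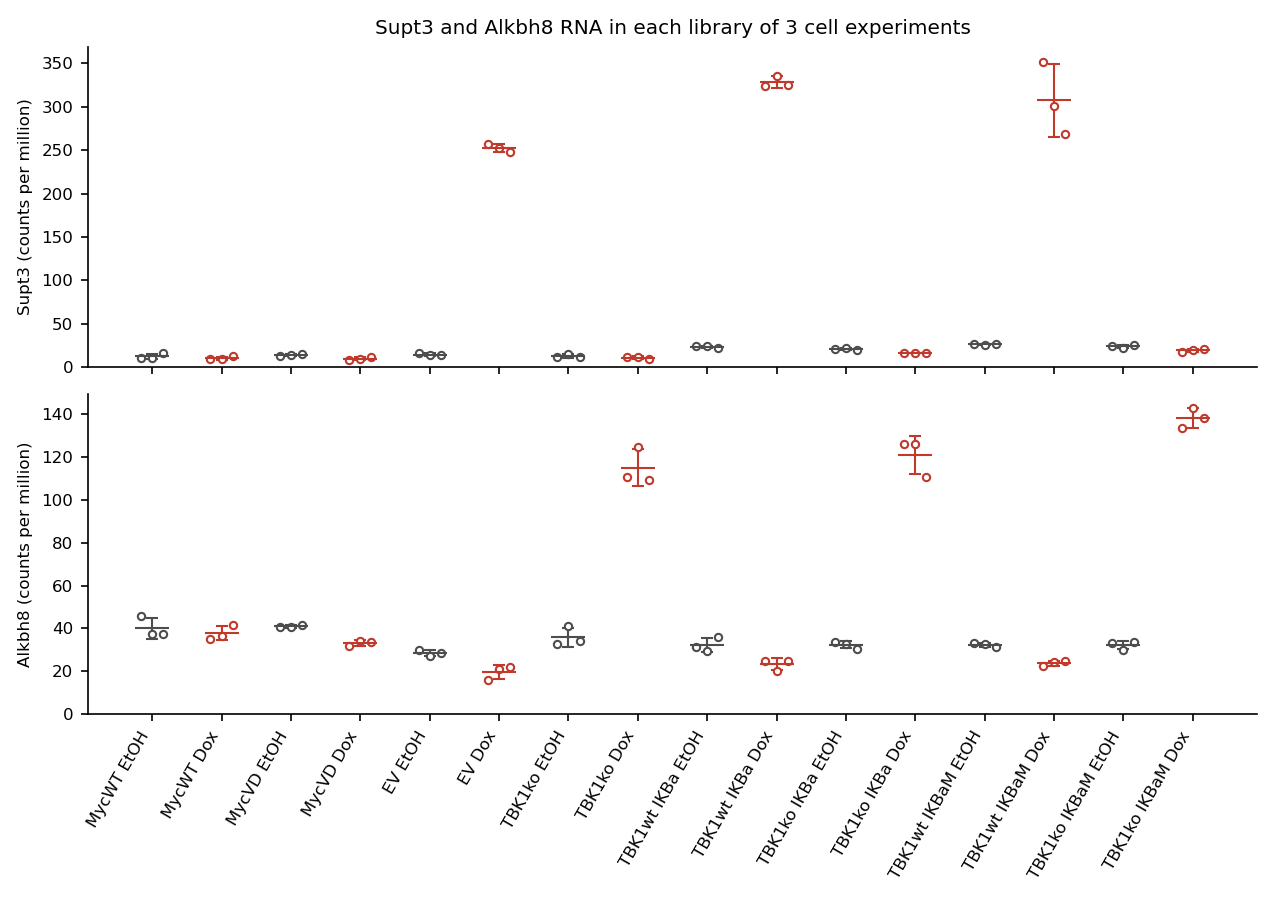
Supt3 and Alkbh8 levels (CPM) per library in the control and doxycycline groups of the MycVD, TBK1 and IKBa tables.

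The IKBa table asks the same of TBK1 in further libraries, and adds a mutant, IKBaM, of the protein that holds NF-kB in the cytoplasm. Whether its lines derive from the EV and TBK1ko cells is not given in the sources used here, so recurrence between the tables is not shown to be independent. Knockdown moved 9714 genes in TBK1ko IKBa cells (4907 up, 4807 down), 10195 in TBK1wt IKBaM cells (5286 up, 4909 down) and 10240 in TBK1ko IKBaM cells (4954 up, 5286 down). In these 3 lines all 37 ribosome biogenesis genes fell (medians -0.92, -0.99 and -1.08), with Ncl at -1.73 ± 0.06, -1.72 ± 0.06 and -1.97 ± 0.06. Tnfaip3 rose from 46.9 to 131 CPM, from 14.9 to 58.6 CPM and from 20.4 to 74.1 CPM, and H2-K1 from 6.97 to 14.2, 14.4 to 35.4 and 3.14 to 9.93 CPM. NF-kB targets rose in 13, 15 and 15 cases and fell in 5, 5 and 4 (medians 0.23, 0.41 and 0.39, adjusted p = 0.0259, 0.0233 and 0.0115). The neutrophil chemokine Cxcl5 went the other way, at -2.50 ± 0.10, -2.64 ± 0.19 and -3.41 ± 0.20. Interferon-stimulated genes rose in 10, 12 and 14 cases (15 in TBK1ko IKBaM adjusted over the list alone, medians 0.53, 0.41 and 0.45, adjusted p = 0.0182, 0.0283 and 0.00587). Lysosome genes rose in 28, 27 and 27 cases (medians 0.72, 0.80 and 0.77). Genes of the KPC up set rose in 1144, 1146 and 1138 cases (medians 0.93, 0.97 and 1.00).

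In TBK1ko IKBa against TBK1wt IKBa cells the response differed at 526 genes (224 higher, 302 lower). The 89 genes of the TBK1-dependent set, chosen in the TBK1 table, rose in 88 cases in TBK1wt IKBa cells (median 1.18) and in 84 in TBK1ko IKBa cells (0.85). As a set the response was lower without TBK1 (median -0.31, 34 lower and 0 higher, adjusted p = 1.7e-30). Csf1 (-1.0 ± 0.13) and Ptgs2 (-0.84 ± 0.08) were lower again, as were Fn1 (-1.16 ± 0.21) and Thbs1 (-1.33 ± 0.17). Myc (0.02 ± 0.09, adjusted p = 0.954), Tnfaip3 (-0.14 ± 0.10, adjusted p = 0.506) and H2-K1 (-0.13 ± 0.15, adjusted p = 0.723) had no difference that passed. The NF-kB list had 1 higher and 5 lower members (2 and 6 adjusted over the list alone, median -0.13, adjusted p = 0.000442). The response of cell cycle genes was higher, as a smaller fall (6 up, 15 adjusted over the list alone, median 0.15, adjusted p = 6.3e-10). In contrast 5 ATF4 stress genes were lower (6 adjusted over the list alone, median -0.12, adjusted p = 0.00205, adjusted p = 0.107 with an estimated correlation). The smaller fall of ribosome biogenesis genes seen in TBK1ko cells did not recur here (2 higher and 1 lower adjusted over the list alone, 1 lower over all genes, median 0.06, adjusted p = 0.0768), with Ncl at 0.00 ± 0.08 (adjusted p = 0.993) and Heatr1 lower by 0.36 ± 0.09 (adjusted p = 0.0252). Supt3 (-4.19 ± 0.13), Runx2 (-3.16 ± 0.12) and Alkbh8 (2.38 ± 0.12) again led. As sets, the KPC up genes had no difference that passed (median -0.02, adjusted p = 0.451), and the down set did weakly (0.06, adjusted p = 0.0357, adjusted p = 0.387 with an estimated correlation).

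In TBK1wt IKBaM against TBK1wt IKBa cells the response differed at 349 genes (148 higher, 201 lower), and the TBK1-dependent set had no difference that passed (7 higher, 3 lower, median 0.02, adjusted p = 0.283). Without IKBaM doxycycline replicate 1 or IKBa control replicate 1 it did pass (adjusted p = 0.00942 and 0.0424). The chemokine Ccl20 went from 2.33 to 14.3 CPM in IKBaM and from 65.8 to 175 CPM in IKBa cells (difference 1.20 ± 0.21), the collagenase Mmp13 from 14.2 to 45 CPM and from 60.8 to 75.7 CPM (1.35 ± 0.12), and Csf1 differed by 1.01 ± 0.15. Nfkbia itself rose in IKBa and fell in IKBaM cells (difference -1.0 ± 0.09). The NF-kB list as a whole split (2 higher, 5 lower, and 6 and 6 adjusted over the list alone, median 0.04, adjusted p = 0.881). Nfkbia is itself on this list, so its lower response at the raised level of the IKBaM line counts among the lower members. Odc1 (0.48 ± 0.09) and Cdk4 (0.31 ± 0.08) were higher, and Cad (-0.39 ± 0.09), Traf3 (-0.62 ± 0.10) and the mucin Muc5ac (-1.37 ± 0.28) lower. Cell cycle (3 higher, 1 lower, and 9 and 3 adjusted over the list alone, median 0.09, adjusted p = 0.00597, adjusted p = 0.0678 with an estimated correlation) and epithelial lists (1 and 1, with 6 and 1 adjusted over the list alone, 0.23, adjusted p = 0.00921, adjusted p = 0.385 with an estimated correlation) were higher. So were the nucleotide (1 and 1, with 2 and 1 adjusted over the list alone, 0.09, adjusted p = 0.0297) and lysosome lists (1 higher, 2 adjusted over the list alone, 0.09, adjusted p = 0.0297), both with adjusted p = 0.385 with an estimated correlation.

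With both changes, TBK1ko IKBaM against TBK1wt IKBa cells differed at 772 genes (334 higher, 438 lower, but 476 higher and 288 lower with RLE factors). The response of ATF4 stress genes was lower (7 lower, and 1 higher and 13 lower adjusted over the list alone, median -0.32, adjusted p = 2.2e-08), with Asns at -0.77 ± 0.08 and the cystine transporter Slc7a11 at -0.81 ± 0.11. Cell cycle genes fell less (11 higher, 20 adjusted over the list alone, median 0.20, adjusted p = 1.7e-16). Ribosome biogenesis fell slightly more (1 lower, 8 adjusted over the list alone, median -0.08, adjusted p = 0.0136, adjusted p = 0.373 with an estimated correlation). The TBK1-dependent set did not differ here (11 higher, 10 lower, median -0.04, adjusted p = 0.959), nor did the KPC down set (-0.05, adjusted p = 0.107), which passed without TBK1wt IKBa control replicate 1 (adjusted p = 0.00911) or TBK1ko IKBaM control replicate 2 (adjusted p = 0.0312). The up set was slightly higher (90 higher, 37 lower, median 0.03, adjusted p = 0.00577, fry adjusted p = 0.0564). These 3 differences share the TBK1wt IKBa libraries and are not independent. Leaving out 1 library moved the count of 526 to 249, 339 and 937 (TBK1wt IKBa control replicates 1 to 3), 303 and 315 (its doxycycline replicates 2 and 3), 326 and 345 (TBK1ko IKBa control replicates 1 and 3) and 257 (its doxycycline replicate 2). The count of 349 moved to 132, 203 and 803 (TBK1wt IKBa controls 1 to 3), 209, 199 and 175 (its doxycycline replicates 1 to 3), 162 and 184 (IKBaM controls 1 and 2) and 205, 200 and 2364 (IKBaM doxycycline replicates 1 to 3). The count of 772 moved to 513 (TBK1wt IKBa doxycycline replicate 1), 495 (TBK1ko IKBaM control 2), 505 and 505 (its doxycycline replicates 1 and 2). With only the groups of the comparison in the fit the counts were 1281 for TBK1ko IKBa and 110 for TBK1wt IKBaM.

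The MycVD table asks whether re-expressed Myc-WT returns the response and whether Myc-VD does so equally. In MycWT cells Myc rose by 1.46 ± 0.24 (adjusted p = 0.00796), and the KPC sets had no shift that passed (up set 40 up and 32 down, median 0.06, adjusted p = 0.688, and down set 53 up and 48 down, 0.02, adjusted p = 0.707). The up set did move without MycWT control replicate 2 (adjusted p = 0.0266) or doxycycline replicate 3 (adjusted p = 0.000558), and the down set without doxycycline replicate 2 (adjusted p = 0.0148). Ncl stayed at 2288 against 2465 CPM (0.11 ± 0.12, adjusted p = 0.661), and Nop56 (-0.26 ± 0.10, adjusted p = 0.179) fell only with the replicate block (adjusted p = 0.000482). Of the ribosome biogenesis genes 7 rose (11 adjusted over the list alone, median 0.19, adjusted p = 9.2e-07, adjusted p = 0.88 with an estimated correlation), such as Nol6 (0.70 ± 0.09). In the nucleotide list 7 rose and 1 fell (8 and 1 adjusted over the list alone, 0.12, adjusted p = 0.0187, adjusted p = 0.88 with an estimated correlation). The GTP enzyme Impdh1 rose (60.7 to 165 CPM) and Prps2 fell (-0.49 ± 0.07). Epithelial markers fell (5 down, 7 adjusted over the list alone, -0.31, adjusted p = 0.000282, adjusted p = 0.317 with an estimated correlation). Among them was the keratin Krt19 (752 to 410.5 CPM). Cdkn1a rose (7.69 to 36.4 CPM) and Aurkb fell (-1.37 ± 0.13), as in KPC cells. The interferon (1 up, median -0.06, adjusted p = 0.751) and MHC class I lists (1 up, 3 down, and 2 and 3 adjusted over the list alone, adjusted p = 0.851) had no shift that passed. NF-kB targets (2 up, median 0.2, adjusted p = 0.103) rose with the replicate block (adjusted p = 0.0105), as did H2-K1 (0.56 ± 0.23, adjusted p = 0.178, with the block 0.00754). The count was 1137 (543 up, 594 down), and 4290 with the replicate block (2260 up, 2030 down). It moved to 307 with only the groups of the comparison, and to 675, 754 and 426 without control replicates 1, 2 and 3, and 374 and 496 without doxycycline replicates 1 and 3.

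In MycVD cells Myc rose as far (1.52 ± 0.24), yet part of the KPC response stayed. The KPC up set rose (183 up, 2 down, median 0.43, adjusted p = 8.8e-23, adjusted p = 0.124 with an estimated correlation). The down set fell (2 up, 208 down, median -0.27, adjusted p = 7.2e-24, adjusted p = 0.124 with an estimated correlation). Ncl fell from 2338 ± 131 to 1693 ± 282 CPM (-0.47 ± 0.12, adjusted p = 0.025), Nop56 by 0.64 ± 0.11 and Srsf1 by 0.33 ± 0.07. Ribosome biogenesis genes fell in 9 cases and rose in 1 (13 and 1 adjusted over the list alone, median -0.17, adjusted p = 5.8e-05, adjusted p = 0.583 with an estimated correlation). Spliceosome genes fell in 7 (10 adjusted over the list alone, -0.11, adjusted p = 6.4e-05, adjusted p = 0.486 with an estimated correlation) and cell cycle genes in 9 with 1 up (11 and 1 adjusted over the list alone, -0.10, adjusted p = 0.00172, adjusted p = 0.192 with an estimated correlation). H2-K1 rose from 21.7 to 42.1 CPM (0.96 ± 0.23, adjusted p = 0.0235), H2-D1 by 0.63 ± 0.10 and Ikbke by 0.76 ± 0.21. Lysosome genes rose in 7 cases (13 up and 1 down adjusted over the list alone, 0.25, adjusted p = 3.1e-05, adjusted p = 0.329 with an estimated correlation). Vesicle genes rose in 11 (15 up and 2 down adjusted over the list alone, 0.14, adjusted p = 0.0017, adjusted p = 0.459 with an estimated correlation). Tnfaip3 (0.87 ± 0.46, adjusted p = 0.263) and NF-kB targets passed only with the replicate block (adjusted p = 1.8e-10 and 0.0364). The count was 1817 (854 up, 963 down), 5701 with the block (3012 up, 2689 down), and 984, 722, 716 and 975 without control replicates 1 and 3 and doxycycline replicates 1 and 2.

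Directly compared under doxycycline, MycVD and MycWT cells had no difference in Myc that passed (0.22 ± 0.23, adjusted p = 0.655). Ncl was lower with Myc-VD (1693 ± 282 against 2465 ± 302 CPM, adjusted p = 0.0461), as were Nop16 (-0.64 ± 0.08), Nolc1 (-0.59 ± 0.09), the purine enzyme Gart (-0.56 ± 0.07), Gemin5 (-0.53 ± 0.10) and Prmt5 (-0.41 ± 0.08). Cad (-0.45 ± 0.11, adjusted p = 0.0625) and Srsf1 (-0.29 ± 0.07, adjusted p = 0.0568) passed only with the replicate block (adjusted p = 3.3e-05 and 0.000165). Ribosome biogenesis (8 lower, 34 adjusted over the list alone, median -0.38, adjusted p = 2.5e-24), nucleotide (1 lower, 12 adjusted over the list alone, -0.24, adjusted p = 3.1e-08) and spliceosome genes (2 lower, 20 adjusted over the list alone, -0.22, adjusted p = 2.2e-14) were lower, all with adjusted p = 0.0994 with an estimated correlation. Lysosome genes were higher (2 up, 12 up and 1 down adjusted over the list alone, 0.25, adjusted p = 1.1e-08), among them the sialidase Neu1 (0.51 ± 0.07). So were epithelial markers (0 up, 4 adjusted over the list alone, 0.29, adjusted p = 0.000935) and double-stranded RNA sensing (1 up, median 0.14, adjusted p = 0.0385), again with adjusted p = 0.0994 with an estimated correlation. Vesicle (1 up, 2 adjusted over the list alone, 0.11, adjusted p = 6.5e-06, adjusted p = 0.108 with an estimated correlation), cell cycle (1 down, 2 adjusted over the list alone, -0.06, adjusted p = 0.0069, adjusted p = 0.171 with an estimated correlation) and mitochondrial translation lists (1 down, median -0.17, adjusted p = 5.7e-06, adjusted p = 0.218 with an estimated correlation) moved less. The KPC up set was higher (21 up, median 0.37, adjusted p = 3.3e-27, adjusted p = 0.0998 with an estimated correlation). The down set was lower (75 down, median -0.28, adjusted p = 4.45e-37, adjusted p = 0.0704 with an estimated correlation). Of 211 genes 56 were higher and 155 lower. The authors' deposited table calls 406 (289 and 117), 74 of them here in the same direction.

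The count of 211 was 4088 with the replicate block (2128 up, 1960 down), 850 by DESeq2 (326 up, 524 down) and 0 with only the groups of the comparison. It was 0 without MycWT doxycycline replicates 1 or 3 or MycVD doxycycline replicates 1 or 2, 485 without MycWT replicate 2 and 795 without MycVD replicate 3. As a difference of responses, edgeR called 0 of 17852 genes, with 1867 at an unadjusted p under 0.05, 66 by DESeq2 (13 up, 53 down) and 1751 with the replicate block (881 up, 870 down). With the block Ncl (-0.57 ± 0.16, adjusted p = 0.312) had an adjusted p of 0.000241 and Tnfaip3 of 0.00024. The response of ribosome biogenesis genes was lower in MycVD cells (0 genes, 25 adjusted over the list alone, median -0.38, adjusted p = 9.4e-23), as were the nucleotide (1 adjusted over the list alone, -0.23, adjusted p = 8.4e-07) and spliceosome lists (8 adjusted over the list alone, -0.20, adjusted p = 5.5e-12). Lysosome (2 adjusted over the list alone, 0.29, adjusted p = 2.0e-09) and epithelial lists (0.32, adjusted p = 0.000513) were higher. These 5 lists gave adjusted p = 0.118 with an estimated correlation in the unpaired fit. The interferon (0.27) and MHC class I lists (0.20, 1 up and 1 down adjusted over the list alone) were higher at adjusted p = 0.0322 each (adjusted p = 0.202 and 0.335 with an estimated correlation). Both KPC sets differed (medians 0.39 and -0.30, adjusted p = 4.0e-23 and 3.2e-32, adjusted p = 0.127 and 0.0932 with an estimated correlation).

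Tumors ask whether the response holds in the pancreas. In tumors A edgeR called 0 of 19601 genes. Of these 3806 had an unadjusted p under 0.05, DESeq2 called 977 (613 up, 364 down). The authors' deposited table calls 1125 (782 up, 343 down). Without doxycycline replicate 2 the count was 3, all up. Ncl stood at 461 ± 36.9 against 304 ± 55.8 CPM (adjusted p = 0.133) and Nop56 at -0.58 ± 0.15 (adjusted p = 0.136). As sets, the KPC up set lay higher (1282 genes, 75.1% above 0, median 0.25, adjusted p = 7.8e-13) and the down set lower (927 genes, 8.4% above 0, median -0.30, adjusted p = 2.7e-27). Ribosome biogenesis (15 of 37 adjusted over the list alone, median -0.27, adjusted p = 3.9e-10), nucleotide (6 adjusted over the list alone, -0.23, adjusted p = 8.8e-06), spliceosome (-0.15, adjusted p = 8.2e-05) and cell cycle genes (-0.51, adjusted p = 3.4e-09) were lower. Lysosome (0.23, adjusted p = 1.1e-06) and vesicle genes (0.06, adjusted p = 0.0358) were higher. Markers of endothelial cells (14 of 16 adjusted over the list alone, 1.12, adjusted p = 3.9e-10), macrophages (7 of 23, 0.72, adjusted p = 1.3e-06), fibroblasts (6 of 20, 0.75, adjusted p = 8.3e-07) and mesenchymal cells (3 of 15, 0.84, adjusted p = 7.4e-05) were higher. All these lists gave adjusted p = 0.373 with an estimated correlation.

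Lymphocyte and interferon lists in tumors A were lower. B and plasma cell markers (6 of 11 adjusted over the list alone, median -1.25, adjusted p = 0.00678, adjusted p = 0.469 with an estimated correlation) and T and NK cell markers (-0.59, adjusted p = 0.00155, adjusted p = 0.577 with an estimated correlation) were lower. Interferon-stimulated (1 of 47 adjusted over the list alone, -0.29, adjusted p = 0.00266) and MHC class I genes (-0.25, adjusted p = 0.0174) were lower, both with adjusted p = 0.636 with an estimated correlation. H2-K1 stood at 1493 ± 222 against 1059 ± 549 CPM (adjusted p = 0.412). Double-stranded RNA sensing (1 up adjusted over the list alone, 0.01, adjusted p = 0.292), NF-kB targets (-0.07, adjusted p = 0.997), the ATF4 stress response (-0.15, adjusted p = 0.0821), and mitochondrial translation (-0.09, adjusted p = 0.0671) did not pass. Nor did markers of epithelial (0.22, adjusted p = 0.838), neutrophil (0.27, adjusted p = 0.423), dendritic (-0.26, adjusted p = 0.448), acinar and islet (0.12, adjusted p = 0.903), and adipocyte and muscle cells (4 up and 1 down adjusted over the list alone, 0.79, adjusted p = 0.079). Doxycycline replicate 4 lay at 125 on the first principal component.

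In tumors B 199 of 19570 genes passed (163 up, 36 down), and interferon genes led. The GTPases Gbp2b (38.5 to 174 CPM) and Iigp1 (72.0 to 328.5 CPM) rose, as did Cxcl9, a chemokine for T cells (26.6 ± 9.22 to 165 ± 87.5 CPM), Cxcl10 (1.59 ± 0.28) and the granule protease Gzmb (2.62 ± 0.38). Of 47 interferon-stimulated genes 15 rose (27 adjusted over the list alone, median 0.66, adjusted p = 9.7e-23). H2-K1 rose from 378 ± 89.2 to 1347 ± 781 CPM (adjusted p = 0.0124), B2m from 594 to 1425 CPM and H2-D1 by 1.64 ± 0.23. In all 8 of 24 MHC class I genes rose (14 adjusted over the list alone, 0.68, adjusted p = 1.0e-13). The interferon and MHC class I lists gave adjusted p = 0.118 with an estimated correlation. Epithelial markers rose (3 of 16, 10 adjusted over the list alone, 0.65, adjusted p = 4.1e-06), with E-cadherin, Cdh1, at 0.75 ± 0.11. Ncl did not (-0.09 ± 0.07, adjusted p = 0.626), though the ribosome biogenesis (median -0.16, adjusted p = 1.5e-07) and spliceosome lists (-0.13, adjusted p = 0.000101) were slightly lower, with 0 members past the test and adjusted p = 0.118 with an estimated correlation. The up set of KPC cells was slightly higher (27 up, 3 down of 1280, median 0.07, adjusted p = 0.0233, adjusted p = 0.351 with an estimated correlation). The down set was lower (961 genes, median -0.08, adjusted p = 3.0e-06, adjusted p = 0.094 with an estimated correlation). DESeq2 called 892 genes (607 up, 285 down).

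Other lists in tumors B were mixed. Vesicle (2 up, median 0.14, adjusted p = 9.9e-05) and lysosome genes (0 up, 4 adjusted over the list alone, 0.15, adjusted p = 0.00103) were higher, both with adjusted p = 0.118 with an estimated correlation. The ATF4 stress response (1 up, 7 adjusted over the list alone, 0.26, adjusted p = 5.25e-05, adjusted p = 0.232 with an estimated correlation) was higher, with Atf3 at 1.12 ± 0.18. So was double-stranded RNA sensing (2 up, 3 adjusted over the list alone, 0.09, adjusted p = 0.0424, adjusted p = 0.272 with an estimated correlation), with the DNA and RNA sensor Zbp1 at 1.22 ± 0.23. Endothelial (1 down, 2 adjusted over the list alone, -0.43, adjusted p = 7.1e-06, adjusted p = 0.272 with an estimated correlation) and macrophage markers (1 up, and 2 up and 1 down adjusted over the list alone, -0.25, adjusted p = 0.0424, adjusted p = 0.699 with an estimated correlation) were lower. The VEGF receptor Kdr fell by 0.86 ± 0.17, while Cd68 rose by 0.60 ± 0.11. Fibroblast (-0.56, adjusted p = 0.00125) and mesenchymal markers (1 up and 1 down adjusted over the list alone, -0.40, adjusted p = 0.00422) were lower, both with adjusted p = 0.488 with an estimated correlation. Lists for nucleotides (-0.06, adjusted p = 0.339), NF-kB targets (2 up and 1 down adjusted over the list alone, -0.04, adjusted p = 0.27), the cell cycle (0.04, adjusted p = 0.27) and mitochondrial translation (1 up, median 0.04, adjusted p = 0.382) did not pass. Nor did markers of T and NK (1 up, 2 adjusted over the list alone, 0.54, adjusted p = 0.121), B and plasma (0.15, adjusted p = 0.322), and neutrophil cells (0.82, adjusted p = 0.541). The same held for dendritic (1 up, and 3 up and 2 down adjusted over the list alone, -0.22, adjusted p = 0.258), acinar and islet (2 down adjusted over the list alone, 0.06, adjusted p = 0.167) and adipocyte and muscle cells (2 up adjusted over the list alone, 0.58, adjusted p = 0.201). Doxycycline replicate 6 lay at 116 on the first principal component. The count of 199 moved to 114 without control replicate 3 or 6, 525, 307 and 335 without doxycycline replicates 3, 4 and 6, and 12 and 42 with acinar and epithelial scores as covariates.

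**Figure D5:**
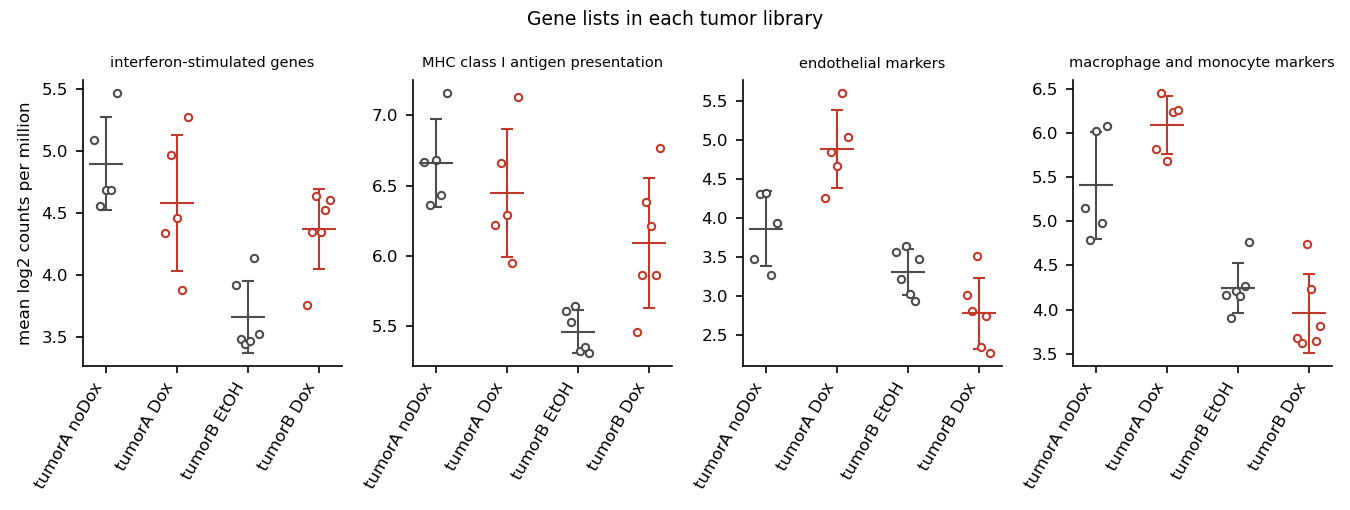
Mean log2-CPM of the interferon-stimulated, MHC class I, endothelial and macrophage lists per tumor library in tumors A and tumors B, with mean and standard deviation per group.

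Both tumor sets together gave 98 of 18917 genes (38 up, 60 down). Among the falls were the host transcripts of small nucleolar RNAs Snhg4 (-0.80 ± 0.11) and Gas5 (-0.74 ± 0.13), Npm1 (-0.46 ± 0.09) and Wdr43 (-0.42 ± 0.08). Myc itself stood at -0.68 ± 0.16 (adjusted p = 0.0608) and Ncl at -0.32 ± 0.08 (adjusted p = 0.0748). Ribosome biogenesis genes were lower (5 down, 22 adjusted over the list alone, median -0.22, adjusted p = 2.2e-18), as were spliceosome genes (2 down, 7 adjusted over the list alone, -0.12, adjusted p = 3.0e-09) such as Srsf7 (-0.33 ± 0.07). Lysosome genes were higher (2 up, 13 adjusted over the list alone, 0.20, adjusted p = 3.0e-09), with the cathepsins Ctsd at 0.49 ± 0.11 and Ctsb at 0.32 ± 0.07, and vesicle genes too (0.10, adjusted p = 8.2e-06). The KPC up set was higher (13 up, 1 down, median 0.16, adjusted p = 2.0e-10) and the down set lower (33 down, median -0.17, adjusted p = 2.1e-27). Interferon (0.27, adjusted p = 0.000104), MHC class I (0.31, adjusted p = 0.00183), cell cycle (-0.20, adjusted p = 1.5e-05) and macrophage lists (1 up adjusted over the list alone, 0.18, adjusted p = 0.00847) all gave adjusted p = 0.641 with an estimated correlation. The nucleotide (3 down adjusted over the list alone, -0.16, adjusted p = 8.0e-05), double-stranded RNA (0.09, adjusted p = 0.0151), adipocyte (1 up, 2 adjusted over the list alone, 0.68, adjusted p = 0.0151) and endothelial lists (0.20, adjusted p = 0.0137) gave adjusted p = 0.259, 0.361, 0.0594 and 0.646 with an estimated correlation.

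The response differed between the tumor sets at 266 genes (101 higher, 165 lower in tumors B). Cxcl9 (3.55 ± 0.63), Gbp2b (3.28 ± 0.61), H2-K1 (2.31 ± 0.49) and B2m (1.60 ± 0.36) were higher, and the endothelial gene Emcn (-2.10 ± 0.41), Kdr (-2.12 ± 0.27) and the macrophage receptor Cd163 (-3.39 ± 0.67) lower. Interferon (11 up, 22 adjusted over the list alone, median 0.99, adjusted p = 3.05e-15), MHC class I (5 up, 12 adjusted over the list alone, 0.83, adjusted p = 1.7e-10) and ATF4 lists (1 up, 2 adjusted over the list alone, 0.51, adjusted p = 0.000237) were higher. Endothelial (8 down, 13 adjusted over the list alone, -1.57, adjusted p = 2.05e-14), macrophage (2 down, and 1 up and 9 down adjusted over the list alone, -1.02, adjusted p = 2.7e-07), fibroblast (11 down adjusted over the list alone, -1.50, adjusted p = 1.1e-07) and mesenchymal lists (6 down adjusted over the list alone, -1.12, adjusted p = 9.4e-06) were lower. These 7 lists gave adjusted p = 0.337 with an estimated correlation. T and NK (4 up adjusted over the list alone, 1.29, adjusted p = 0.00206), cell cycle (0.52, adjusted p = 0.00188), nucleotide (2 up adjusted over the list alone, 0.16, adjusted p = 0.0024) and epithelial lists (1 up and 1 down adjusted over the list alone, 0.69, adjusted p = 0.0434) gave adjusted p = 0.583, 0.681, 0.372 and 0.614 with an estimated correlation. The KPC sets differed too (medians -0.19 and 0.21, adjusted p = 2.5e-05 and 2.3e-07, adjusted p = 0.0852 each with an estimated correlation). The experiments differ in more than treatment, since controls of tumors B are labelled EtOH and those of tumors A noDox, and the labels leave the duration of doxycycline open for tumors B.

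Counts in the joint tumor fits hung on single libraries. The count of 98 moved to 44, 11 and 49 without noDox replicates 1 and 5 and doxycycline replicate 2 of tumors A. It moved to 56, 33, 21, 45, 53 and 52 without control replicates 1 to 6 of tumors B, and to 53, 37, 39, 238 and 158 without its doxycycline replicates 1, 2, 3, 4 and 6. DESeq2 gave 563, limma on the authors' deposited combined table gave 293 (29 up, 264 down), and leaving out both tumors that lay apart 191 (112 up, 79 down). The count of 266 moved to 31, 173, 460, 77 and 129 without noDox replicates 1 to 5 and to 104 and 103 without doxycycline replicates 3 and 4 of tumors A. It moved to 90, 170, 79, 143, 133 and 38 without control replicates 1 to 6 and to 83, 923, 143 and 126 without doxycycline replicates 2 to 5 of tumors B. DESeq2 gave 878.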

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

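Tests of the tumor pattern, of a response in every wild-type line, of TBK1 dependence and of incomplete replacement were chosen after the result was seen, as were the splits for KPC, EV, TBK1ko, MycWT and MycVD cells and for both direct comparisons under doxycycline; the other tests were written before.

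Single libraries stood apart from their group by a Dixon test at 7 of 100 groups of values, where chance alone does so in about 1 in 20. In tumors A, noDox replicate 3 had 9.40 M counts (others 9.50 to 9.54). Doxycycline replicate 4 of tumors A had a mean log2-CPM of 2.40 for the adipocyte and muscle list (others 3.25 to 3.57). In tumors B, control replicate 5 had Myc at 73.8 CPM (others 100.7 to 109.6), and control replicate 3 a spliceosome list mean of 6.13 (others 5.98 to 6.02). Doxycycline replicate 1 of tumors B had an interferon list mean of 3.76 (others 4.35 to 4.64). Doxycycline replicate 6 had a lysosome list mean of 6.51 (others 6.72 to 6.83) and a mitochondrial translation list mean of 5.23 (others 4.89 to 4.99).

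The other results listed here are differences of a response between groups. Genes whose response differed numbered 266 between the tumor sets, 649 between TBK1ko and EV cells, and 526, 349 and 772 for TBK1ko IKBa, TBK1wt IKBaM and TBK1ko IKBaM against TBK1wt IKBa cells. Lists that differed numbered 11 between the tumor sets, 10 between MycVD and MycWT cells, 9 between TBK1ko and EV cells, and 8, 4 and 3 in the IKBa table in the same order. With an estimated correlation the first 3 of these counts were 0, 0 and 1, and those of TBK1ko IKBa and TBK1wt IKBaM cells 3 and 0. The KPC up and down sets differed by medians of -0.19 and 0.21 between the tumor sets, 0.39 and -0.30 between MycVD and MycWT cells, and -0.17 and 0.22 between TBK1ko and EV cells. In the IKBa table the down set differed by 0.06 and the TBK1-dependent set by -0.31 in TBK1ko IKBa cells, and the up set by 0.03 in TBK1ko IKBaM cells.

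Interferon and MHC class I genes rose in tumors B and not in tumors A. Fewer tumor cells in tumors B under doxycycline stays open. The endothelial median of -0.43 (adjusted p = 0.272 with an estimated correlation) covers vessels only, and epithelial markers (0.65) rose in KPC cells too. Acinar or epithelial covariates lowered the count of tumors B. More lymphocytes or neutrophils (medians 0.54 and 0.82, adjusted p = 0.121 and 0.541) were not excluded. The tumors that lay apart were argued against as the cause, since without both of them the interferon list still differed at adjusted p = 5.19e-12. This p-value rests on the preset correlation, and with an estimated one the difference over all libraries was not called (adjusted p = 0.337). A difference between the experiments stays open, since their control labels differ and the duration of doxycycline is open for set B only. Control tumors of set B had interferon list means of 3.45 to 4.14 against 4.56 to 5.47 in set A.

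Supt3 and Runx2 rose under doxycycline in some lines with wild-type TBK1 and in no TBK1ko line. Supt3 went from 14.3 to 253 CPM in EV, 23.4 to 328.5 in TBK1wt IKBa and 26.4 to 307 in TBK1wt IKBaM cells, but from 12.9 to 10.9, 20.6 to 15.8 and 23.8 to 19.1 in the TBK1ko lines. A response in every line with wild-type TBK1 was argued against by Runx2 at -0.38 in KPC cells, and dependence on TBK1 could not be told from a trait of lines that the tables may share (Supt3 at -0.38 in TBK1ko IKBa cells). A local change around both genes, such as a doxycycline-driven construct inserted there, could not be settled either: 0 of 6 tested neighbours had a difference with a fall of at least 1, yet Clic5, chosen after its values were seen, differed by -0.65 ± 0.15 (adjusted p = 0.0258), a weak hint since it also rose in KPC (1.29), TBK1ko IKBa (1.44) and TBK1wt IKBa cells (1.32). The prediction met both of its bounds and was too narrow, since a change confined to the pair moves no neighbour.

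Some genes moved in KPC and in MycWT cells alike, although the latter re-express Myc. An effect of doxycycline or of the shRNA that does not pass through MYC may take part: 410 genes passed in both in the same direction (186 up against 171 expected, 224 down against 188) and 364 in opposite directions, a small excess. These MycWT calls are from the fit without the replicate block, and the overlap was not run with it. Incomplete replacement of MYC was argued against for most ribosome biogenesis genes, whose quartiles in MycWT cells were 0.07 and 0.31, though 4 of 37 lay below 0 and Nop56 fell with the block (-0.26, adjusted p = 0.000482). The rise of this list was not called with an estimated correlation (adjusted p = 0.88).

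Groups of 3 against 3 allow only 10 splits, too few to weigh chance. Only the real one reached the count in all 11 such comparisons (highest other 0). Chance was argued against for tumors B (1 of 100 splits as large, highest other 1), both tumor sets together (1 of 60, highest other 1) and their difference (1 of 60, highest other 0). For tumors A and the difference of MycVD and MycWT cells 100 of 100 splits reached 0 genes (highest other 1 and 304). With a real count of 0 these splits say nothing about chance. The MycVD splits were also unpaired, and the blocked fit called 1751 genes. For TBK1ko against EV cells 8 of 100 splits were as large (highest other 3943), and for the 3 differences of the IKBa lines 9 of 60 (3845), 7 of 60 (1049) and 7 of 60 (5409). These splits exchange lines within a treatment and so also measure the lines, so this test cannot weigh chance. Which splits gave the large counts was not examined.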

How the results depend on the processing

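Leaving out both tumors that lay apart and the replicate block of the response sets were chosen after the result was seen; every other alternative was fixed before. Of 14847 gene values under the alternatives 13595 kept direction and side of the threshold, 1182 were weaker, 70 stronger and 0 reversed. For lists it was 4450 of 4902 (280 weaker, 172 stronger, 0 reversed), for response sets 619 of 653 (27 weaker, 7 stronger, 0 reversed), for counts of genes 183 of 289, for counts of lists 241 of 270 and for correlations and overlaps 20 of 24. DESeq2 gave no adjusted p for 38 of the named-gene values. Depth limits genes of low level most. The causes of the changes below were not tested.

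Gene counts moved by over 1.5 times as follows. Tumors A: 977 by DESeq2, 0 to 3 with a library left out. Tumors B: 892 by DESeq2, 12 with an acinar and 42 with an epithelial covariate, 114 to 525 with a library left out. Both sets: 563 by DESeq2, 3 with the experiment left out, 293 by limma on the combined table, 191 without both tumors that lay apart, 11 to 238. Their difference: 878 by DESeq2, 132 without both tumors, 31 to 923. MycWT: 4290 with the replicate block, 307 with only the groups compared, 374 to 919. MycVD: 5701 with the block, 716 to 2006. MycVD against MycWT: 850 by DESeq2, 4088 with the block, 0 with only the groups compared, 0 to 795. Their difference of responses: 66 by DESeq2, 1751 with the block. TBK1ko minus EV: 1242 by DESeq2 (818 up, 424 down), 99 to 2722. TBK1ko IKBa: 1281 with only the groups compared, 249 to 937. TBK1wt IKBaM: 110 with only the groups compared, 132 to 2364. TBK1ko IKBaM: 495 to 854.

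Counts of lists fell with an estimated correlation from 13 to 6 (KPC), 14 to 0 (tumors A), 13 to 1 (tumors B), 12 to 4 (both), 11 to 0 (their difference), 3 to 0 (MycWT), 5 to 0 (MycVD), 9 to 0 (MycVD against MycWT), 10 to 0 (their difference), 8 to 2 (TBK1ko against EV), 9 to 1 (TBK1ko minus EV), 8 to 3 (TBK1ko IKBa) and 4 to 0 (TBK1wt IKBaM). With fry they were 2 (tumors A), 6 (tumors B), 6 (both), 1 (their difference), 1 (MycWT), 5 (MycVD minus MycWT), 15 (TBK1ko against EV), 1 (TBK1wt IKBaM) and 5 (TBK1ko IKBaM). RLE factors gave 7 for TBK1wt IKBaM, and leaving out both tumors 7 for the difference of the tumor sets. A library left out gave 2 to 5 (MycWT), 2 to 8 (TBK1wt IKBaM) and 2 to 5 (TBK1ko IKBaM).

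Adjusted p-values of response sets that crossed the threshold were these. With an estimated correlation: tumors B 0.351 (up) and 0.094 (down), difference of the tumor sets 0.0852 and 0.0852, MycVD 0.124 and 0.124, MycVD against MycWT 0.0998 and 0.0704, their difference 0.127 and 0.0932, and TBK1ko IKBa 0.387 (down). With fry: tumors B 0.371 (up), MycVD against MycWT 0.0528 (up), their difference 0.153 (up), TBK1ko IKBa 0.207 (down) and TBK1ko IKBaM 0.0564 (up). With a minimum of 0.5: TBK1ko IKBa 0.0523 (down) and TBK1ko IKBaM 0.277 (up). With a library left out: tumors B 3.35e-05 to 0.172 (up), MycWT 0.000558 to 0.578 (up) and 0.0148 to 0.855 (down), TBK1ko IKBa 0.0142 to 0.198 (down), TBK1ko IKBaM 0.00911 to 0.376 (down), and the TBK1-dependent set in TBK1wt IKBaM 0.00942 to 0.963. Among genes of mean log2-CPM of at least 2, correlations moved from 0.86 to 0.93 (EV and TBK1wt IKBa) and 0.40 to 0.47 (TBK1wt IKBa and tumors A), and genes down in tumors B and in EV or TBK1wt IKBa cells from 5 to 3 and 7 to 4.

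The replicate block gave 9929 genes in KPC, 10247 in EV, 7948 in TBK1ko, 6932 for TBK1ko against EV, 534 for TBK1ko minus EV, 10365 in TBK1wt IKBa, 9773 in TBK1ko IKBa, 10227 in TBK1wt IKBaM and 10277 in TBK1ko IKBaM cells, and 618, 440 and 806 for the 3 differences of the IKBa table. Same-numbered libraries did not deviate together there (correlations -0.045 to 0.042 in KPC, -0.28 to 0.275 in the TBK1 and -0.178 to 0.195 in the IKBa table), so these share only a number. In the MycVD table the block changed further calls, all at the list or gene level: lists of the ATF4 stress response (adjusted p = 0.00525) and mesenchymal markers (0.00223) for MycVD against MycWT, and of double-stranded RNA sensing (0.0469), the ATF4 stress response (0.0153) and mesenchymal markers (0.00329) for their difference. Of named genes it added Tbk1 (0.0034), B2m (0.00825), Cad (0.0113) and Tnfaip3 (0.00701) in MycWT cells, and Tbk1 (4.33e-05), Vamp4 (0.00821), B2m (0.0163), Cad (0.00652) and Oasl1 (0.0015) in MycVD cells. For MycVD against MycWT it added Ikbke (0.000909), Nop56 (1.71e-05), Cdk4 (0.0295) and Tnfaip3 (4.71e-07), and for their difference Ikbke (0.00216), Srsf1 (0.00321), Cad (0.00246) and Nop56 (0.0017). It ended the calls of Muc5b (0.0512) and Mrc1 (0.0549) in MycWT cells. It changed no call of a response set. No paired analysis was possible for the tumors because their columns carry no shared numbers.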

Other observations

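The levels compared here were looked at after the results were seen and were not tested.

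Some genes stood lower in the IKBaM line before any doxycycline, while Nfkbia stood higher. In TBK1wt IKBa and TBK1wt IKBaM controls Tnfaip3 stood at 41.4 ± 2.98 and 14.9 ± 0.706 CPM, Ccl20 at 65.8 and 2.33 CPM, and H2-K1 at 31.6 and 14.4 CPM. These genes rose under doxycycline in both lines, so a rise from a lower level remained where IKBa was mutant. In the TBK1ko lines H2-K1 stood at 5.36 CPM (TBK1 table), 6.97 CPM (IKBa) and 3.14 CPM (IKBaM), below the 31.7 and 31.6 CPM of EV and TBK1wt IKBa controls, and rose from there.

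Some genes best known from immune cells were read in the cultured carcinoma lines. The chemokine receptor Ccr9 fell from 265 ± 3.10 to 86.6 ± 3.17 CPM in KPC cells, from 377 ± 33.6 to 176.6 ± 0.952 CPM in EV cells and from 335 ± 4.28 to 180.7 ± 7.03 CPM in TBK1ko cells. The actin-severing protein Gsn, on the fibroblast list, rose from 182 ± 8.5 to 996 ± 17.9 CPM in KPC cells. Markers on the immune and stromal lists can thus come from the tumor cells themselves.

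Across genes, which are not independent replicates, log2 fold changes in tumors A correlated with those in KPC cells at 0.47, EV cells at 0.41 and TBK1wt IKBa cells at 0.40; for tumors B the values were 0.12, 0.10 and 0.07, and tumors A and B correlated at -0.19. Genes that rose in tumors B and in KPC cells numbered 71 (30.9 expected), and those that fell in both 9 (8.1 expected).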
